A study of Mus musculus with 12 samples.

How the data were processed

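Poly(A) RNA of 12 mouse retina libraries was measured by sequencing, in 4 groups of 3 libraries: lasered eyes on day 3, control eyes on day 3, lasered eyes on day 7 and control eyes on day 7. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA came from retina samples and the libraries were made with a directional kit, which keeps the strand of origin. STAR 2.7.0, edgeR 3.28.0 and the mm10 build are named, without a role, per the submitters' processing notes. The counting tool, its use of strand and the annotation release are not given in the sources used here.

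The deposited values are a signal per gene, in 1 table per day, each with 54367 genes, and the tables are named as TPM by the authors. Column sums ran from 953049 to 1045986, so the deposited signal is not TPM in the strict sense. Multiplying each value by the gene's union exon length in GENCODE M21, in which 53681 of the 54367 genes have the same start and end, gave whole multiples of 1 step per library once a factor was taken out. That factor took 6 values, cycling with the position of the gene in the table, and lay between 0.955 and 1.04 on day 3 and between 0.962 and 1.05 on day 7. The largest shift it put between the groups of a day was 0.05 on the log2 scale on day 3 and 0.0022 on day 7. Which step of the authors' processing made it is not given in the sources used here. The main tests kept the deposited values, and undoing the factor was an added alternative.

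The same steps gave the depth. Reads assigned to genes were recovered as 9282013 to 12515844 per library on day 3 and 23886219 to 31092913 on day 7. Of the values under 20 reads, 74473 on day 3 and 44375 on day 7, between 98.9% and 99.1% per library came out whole within 0.05, where chance gives 10%. A count of 3 reads in a gene with 1 kb of exons corresponds to a value of 0.445 to 0.605 on day 3 and 0.292 to 0.380 on day 7. These limits cover counting error only. In total 183 genes share a symbol with another gene, and 0 columns lacked a matching sample.

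Each day was fitted within its own table with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior variance, 2-sided) on log2(value + 1), for genes with a mean of at least 1 over the 6 libraries of the day. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The difference between the days was the interaction of day and laser over 12 libraries, for genes with a mean of at least 1 over all of them. The unit assumed when the tests were fixed was TPM, and the same test was kept for the signal. Other computing used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

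Before the data were examined, 31 lists with 477 genes were fixed from textbook knowledge, with 0 genes in more than 1 list. They cover angiogenic factors and receptors, endothelial cells, pericytes and smooth muscle, microglia, infiltrating monocytes and macrophages, neutrophils, lymphocytes, cytokines with chemokines and adhesion molecules, complement, interferon response, antigen presentation, reactive gliosis, Müller glia, rods, cones, bipolar cells, amacrine and horizontal cells, retinal ganglion cells, neuronal injury response, retinal pigment epithelium with melanocytes, lens, corneal and conjunctival epithelium, skeletal muscle, erythrocytes, extracellular matrix, cell cycle, immediate early and heat shock genes, hypoxia and glycolysis, circadian clock, mitochondrially encoded genes, and Y-linked genes with Xist. Lists with at least 4 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares the genes of a list with all other tested genes. Camera with an estimated correlation and limma's fry were run beside it. Members were also adjusted over the list alone. The lists on the difference between the days were tested with camera as well, an addition made after the data were seen.

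The genes named were also fixed in advance. They are, per day, the 6 largest rises and the 6 largest falls among genes past the threshold without overlap between groups and with a gene name other than a predicted one. Where fewer passed, those and the 3 smallest p-values of that direction were taken. To these come 12 fixed genes (among them Vegfa, Pgf, Kdr, Angpt2, Gfap, Serpina3n, C3, Ccl2, Il1b, Aif1 and Rpe65), up to 3 members with the smallest p of each list that passed or is described, and the 5 smallest p-values of the interaction. Some genes that this rule names are not reported here. Coordinates are from the deposited tables, counted from 1, on mm10.

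The design text makes the untreated left eye of each mouse the control of its lasered right eye, while the labels do not state that equal replicate numbers mark the same mouse. Deviations from the group means correlated between libraries of equal number by 0.485, 0.559 and 0.128 on day 7, all over 0.1, and by 0.0413, 0.0162 and 0.0766 on day 3. With GC trends removed these were 0.313, 0.332 and 0.0754 on day 7 and 0.0453, -0.0064 and 0.0495 on day 3. The tests reported have no block, and the fit with the replicate number as a block is given where it changes a call.

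The alternatives chosen before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5, median-of-ratios rescaling, quantile normalization, the replicate block, a joint fit of 12 libraries, no trend in the prior variance, and each library left out in turn. Added after the data were seen were the factor undone, limma-voom on the recovered reads of genes with a mean of at least 10, each library's loess trend on GC content (span 0.5) removed, alone and with the block, library weights estimated by limma, and genes with at least 200 bases of exons. Tests on raw counts were not run, because the deposited values are not raw counts.

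The procedure was tested on simulated data made from means and the spread within groups. The means were those of the controls of each day, and of all 12 libraries for the interaction. Changed genes were drawn only from those of higher value, so the recovery does not cover low genes. On day 3 (16786 genes) the procedure recovered 90 of 100 genes changed 4-fold and 98 of 100 changed 16-fold, with 11 false calls. On day 7 (15592 genes) it recovered 80 and 100 of 100, with 9 false calls, and for the interaction (17611 genes) 75 and 96 of 100, with 6 false calls. A shifted simulated list had an adjusted p of 1.34e-14 on day 3 and 4.73e-23 on day 7, with 0 other lists called. The simulated genes varied independently of each other, so this does not cover lists whose genes move together. In the real data of day 3 the estimated correlation was 0.96 for the interferon response and 0.94 for reactive gliosis.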

Results

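The retinas of C57BL/6 mice aged 8 to 12 weeks were profiled after laser photocoagulation of the right eye with a 532 nm laser (spots of 75 µm, 0.1 s). The left eye received no laser and served as control. Retinas were taken on day 3 and day 7, giving 3 libraries per group and 12 in all, and the title of the series names retinal angiogenesis in the inflammatory stage as its subject. Reads assigned to genes ranged from 9282013 to 12515844 per library on day 3 and from 23886219 to 31092913 on day 7. The labels give 3 retina samples per group without stating that equal numbers mark one animal, so p-values measure the spread between these samples. Lasered retinas were compared with controls of the same day, because each day has a table of its own.

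The first comparison asked which genes differed between lasered and control retinas on day 3. The lists of reactive gliosis, interferon response, microglia and chemokines were higher relative to other genes by camera, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.521). Gfap, the intermediate filament of astrocytes and reactive Müller glia, went from 6.48 ± 1.91 (SD, n = 3) in controls to 412, 93.8 and 104 in the lasered retinas. Edn2, which encodes the vasoactive peptide endothelin 2, went from 1.003 ± 0.286 to 77.2, 23.0 and 32.1, and the monocyte chemokine Ccl12 from 2.26 ± 0.675 to 61.2 ± 22.1 (SD, n = 3). The rod and cone lists were lower relative to other genes by camera (adjusted p = 0.521 for both with an estimated correlation), with 0 markers that fell over either list alone and no call by fry (adjusted p = 0.395 and 0.274). The libraries were unequal: the response of lasered replicate 1 exceeded that of the other lasered libraries in most immune and glial groups.

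Of 16786 genes tested on day 3, 24 rose and 1 fell. The largest rises among named genes were Gfap (log2 fold change 4.45, SE 0.54, adjusted p = 0.0450), Edn2 (4.31, SE 0.41, adjusted p = 0.0278), Ccl12 (4.21, SE 0.28, adjusted p = 0.0188), Fcrls, an Fc receptor-like gene enriched in microglia (2.97, SE 0.36, adjusted p = 0.0450), Crym, a thyroid hormone-binding protein (2.94, SE 0.36, adjusted p = 0.0450), and CT025671.4, a long noncoding RNA (2.93, SE 0.26, adjusted p = 0.0278). Gfap (ENSMUSG00000020932) lies on chromosome 11 from 102887336 to 102900912, Edn2 (ENSMUSG00000028635) on chromosome 4 from 120161206 to 120167360, and Ccl12 (ENSMUSG00000035352) on chromosome 11 from 82101845 to 82103400. Ccl12 is a close relative of Ccl2, so reads of the pair may have been split by the counting. Of the 25 genes, 12 were protein-coding and 4 had under 200 bases of exons. The gene that fell was Gm26446, a small nuclear RNA chosen after its values were seen (-1.81, adjusted p = 0.0447). When only genes with at least 200 bases of exons were tested, 0 fell. No fall with a given name passed; the smallest p-values were those of AC154518.1 (-1.27, adjusted p = 0.0883), Mir8116 (-1.83, adjusted p = 0.0915) and Olfr1304-ps1 (-1.76, adjusted p = 0.0936). In 31.6% of tested genes the groups did not overlap, where chance gives 10%, and 3861 genes had an unadjusted p under 0.05, 3476 of them higher.

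The size of this count depended on the fit and on single libraries. With the replicate number as a block 0 genes passed (smallest adjusted p = 0.0574, 3491 at an unadjusted p under 0.05), without the filter 0, with GC trends removed 1, with voom 3, after quantile normalization 12 and median-of-ratios rescaling 13, while library weights gave 369 and the joint fit of 12 libraries 1016. Without lasered replicate 1 the count was 294, without lasered replicate 3 it was 1, and without control replicate 1, 2 or 3 it was 0, 0 and 0. The median log2 fold change of all genes was 0.16, and -0.01 after median-of-ratios rescaling and -0.07 after quantile normalization.

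All 19 tested genes of the reactive gliosis list rose when adjusted over the list alone, and 2 of them, Edn2 and Gfap, over all genes (camera adjusted p = 8.47e-11; adjusted p = 0.521 with an estimated correlation). A2m, a protease inhibitor, was higher by 2.59 (SE 0.34, list-alone adjusted p = 6.93e-04). Serpina3n, a serine protease inhibitor of reactive astrocytes, stood at 5.83 ± 1.81 (SD, n = 3) in controls and at 1147, 67.7 and 124 in lasered retinas, a log2 difference of 5.01 that did not pass over all genes (adjusted p = 0.0883). Serpina3n belongs to a multigene family, so its value is uncertain. The mean of the list lay above controls by 4.52, 1.94 and 2.32 in lasered replicates 1, 2 and 3. In the interferon response list all 20 tested genes rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.99e-09; adjusted p = 0.521 with an estimated correlation). Examples are Bst2, an antiviral membrane protein (4.40, list-alone adjusted p = 0.00321), Usp18 (3.80, 0.00321) and Irf9, a transcription factor of interferon signalling (3.56, 0.00321). The lasered means of that list were 4.76, 1.98 and 2.14 above controls.

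Of 16 microglia markers 13 rose when adjusted over the list alone, 1 of them, C1qb, over all genes (2.82, SE 0.29, adjusted p = 0.0278; camera adjusted p = 4.61e-07; adjusted p = 0.521 with an estimated correlation). C1qc (1.73, list-alone adjusted p = 0.00174) and Trem2 (1.29, 0.00174) were among them. Aif1, a marker of microglia and macrophages, was higher by 1.92 without passing over all genes (adjusted p = 0.0883). Of 16 markers of infiltrating monocytes and macrophages 5 rose, with Cd68 at 2.74 (list-alone adjusted p = 0.00217), Lgals3 at 3.38 (0.00664) and Spp1 at 3.30 (0.0152), and 11 did not pass (camera adjusted p = 1.02e-04; adjusted p = 0.523 with an estimated correlation). Their lasered means were 3.95, 0.94 and 1.35 above controls. For this list the count was 2 without control replicate 1 or 3 and 12 without lasered replicate 2. In controls Cd68 was at 5.21, Lgals3 at 0.586 and Spp1 at 29.4, and whether cells infiltrated the retina was not tested. None of 5 neutrophil markers passed (camera adjusted p = 0.114), while 5 of 5 rose over the list without lasered replicate 2, and their lasered means differed by 5.89, 0.14 and 2.36. S100a8 was at 0.763 ± 0.626 in controls and 167 ± 268 (SD, n = 3) in lasered retinas. With the replicate block the neutrophil list passed (adjusted p = 0.0424), as it did with GC trends removed (adjusted p = 0.0244) and without lasered replicate 2 (adjusted p = 0.0014). In the main fit it did not pass with an estimated correlation (camera adjusted p = 0.582) or by fry (adjusted p = 0.268).

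Of 17 cytokines, chemokines and adhesion molecules 13 rose when adjusted over the list alone, 1 of them, Ccl12, over all genes (camera adjusted p = 3.04e-06; adjusted p = 0.521 with an estimated correlation). Ccl4 was higher by 2.81 (list-alone adjusted p = 0.00794) and Ccl3 by 2.19 (0.0128). Ccl2 read 0, 0 and 0.173 in the controls and 181, 6.499 and 11.5 in the lasered retinas (1071, 50 and 70 reads) and did not pass over all genes (adjusted p = 0.0938). Il1b was listed at 0 in the 3 controls, where 3 reads correspond to 0.224 to 0.321, and had 549, 2 and 19 reads in the lasered retinas (adjusted p = 0.283). Of 10 complement genes 8 rose, with C4b passing over all genes (2.01, SE 0.20, adjusted p = 0.0278), and Serping1 (2.93, list-alone adjusted p = 0.00262) and C3ar1 (2.23, 0.00646) over the list (camera adjusted p = 1.02e-04; adjusted p = 0.521 with an estimated correlation). C4b shares most of its sequence with C4a, which makes its count uncertain. C3 was higher by 1.47 and did not pass (adjusted p = 0.243). In antigen presentation 11 of 13 rose, among them H2-D1 (3.77), H2-K1 (3.46) and B2m (2.53), each at a list-alone adjusted p of 0.0171, and 0 over all genes (camera adjusted p = 1.84e-05; adjusted p = 0.521 with an estimated correlation). H2-D1 and H2-K1 are near-identical in parts and their counts are uncertain. Leaving out single controls lowered these counts: antigen presentation fell to 0 without control replicate 1 or 3, cytokines to 8, 3 and 1 without control 1, 2 and 3, and complement to 4 without control 2 and 5 without lasered replicate 1.

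Photoreceptor markers lay below other genes. Of 21 rod markers 18 had negative differences, with a median of -0.52, and 0 passed adjusted over the list alone (camera adjusted p = 1.93e-07; adjusted p = 0.521 with an estimated correlation). Gnb1, a G protein subunit also used outside rods, differed by -1.23 (adjusted p = 0.125), and Cngb1 by 0.80 (adjusted p = 0.178). Rod means of lasered replicates 1, 2 and 3 were -1.09, 0.06 and -0.31 from controls, and without lasered replicate 2 the number of rod markers that fell was 6. The rod median was -0.19 without lasered replicate 1 and -0.84 without lasered replicate 2, and the cone median -0.31 without lasered replicate 1. Of 12 cone markers 11 were negative, with a median of -0.49 (camera adjusted p = 3.09e-06; adjusted p = 0.521 with an estimated correlation), and the lasered means were -1.56, -0.24 and -0.32. Gnat2, the cone transducin, differed by -1.11 and Kcne2 by -0.91, with 0 falls passing over the list alone, while Gnb3, which bipolar cells also express, rose by 0.90 (list-alone adjusted p = 0.0114). Without control replicate 1 or 3 Gnb3 did not pass, and without lasered replicate 1 the number of cone markers that fell was 4. Retinal pigment epithelium and melanocyte markers had a median of -0.85 with 0 of 12 passing (camera adjusted p = 5.78e-05; adjusted p = 0.521 with an estimated correlation), and lasered means of -1.59, -0.93 and 0.29. Rpe65, the visual cycle isomerase, was at 39.1 ± 10.1 in controls and at 2.11, 19.3 and 57.9 in lasered retinas (-1.34, adjusted p = 0.427), and Pmel, a melanosome protein, differed by -1.14. The pigment epithelium median was -0.54 without control replicate 2, -0.31 without lasered replicate 1 and -1.33 without lasered replicate 3, where the number of these markers that fell was 8. Mitochondrially encoded genes took 15.7%, 17.3% and 19.0% of the signal in lasered retinas 1, 2 and 3 and 22.7%, 22.6% and 20.9% in the controls. Of these 13 genes mt-Co3 (-0.64), mt-Co1 (-0.52) and mt-Cytb (-0.57) fell, each at a list-alone adjusted p of 0.0403 (camera adjusted p = 5.20e-07; adjusted p = 0.521 with an estimated correlation). The mitochondrial list lost its call after quantile normalization (adjusted p = 0.910), and the number of its genes that fell was 2 without lasered replicate 3 and 0 without any other library.

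Bipolar cell markers had a median of -0.11 with 0 of 12 passing, Car8 at 0.82 and Scgn at -0.43 among them (camera adjusted p = 0.0402; adjusted p = 0.521 with an estimated correlation), and this call ended with the replicate block (adjusted p = 0.0668; 0.0759 with GC trends removed as well), without the filter (0.141), in the joint fit (0.0649), with the cyclic factor undone (0.0595) and with library weights (0.0812). It also ended without control replicate 1 (0.0604) or 2 (0.103) and without lasered replicate 1 (0.111) or 3 (0.0539). The bipolar median was -0.06 without control replicate 3, -0.05 without lasered replicate 1 and -0.18 without lasered replicate 2. Of 13 Müller glia markers 4 rose, Crym over all genes and Apoe (1.16, list-alone adjusted p = 0.00209), Dkk3 (0.55, 0.0110) and Kcnj10 (0.65, 0.0110) over the list. Camera did not set the list apart from other genes (adjusted p = 0.442), while fry passed it (adjusted p = 0.00389). Of 10 retinal ganglion cell markers Nefl, a neurofilament, rose (0.77, list-alone adjusted p = 0.0197; camera adjusted p = 0.802). The count of ganglion cell markers was 0 without control replicate 1, lasered replicate 2 or lasered replicate 3, and 2 without lasered replicate 1. In the neuronal injury response 7 of 10 rose, among them Atf3 (2.69, list-alone adjusted p = 0.00900), Gap43 (0.62, 0.00900) and Stmn4 (0.55, 0.0264), and 0 over all genes (camera adjusted p = 0.00145; adjusted p = 0.521 with an estimated correlation). That count ranged from 2 without control replicate 1 or 3 to 9 without lasered replicate 3, and was 4 without control 2, lasered replicate 1 or lasered replicate 2.

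For vessel growth, 2 of 16 angiogenic factors and receptors rose when adjusted over the list alone: Fgf2, a mitogen of many cell types (2.26, list-alone adjusted p = 0.0264), and Kdr, the main receptor of Vegfa (0.99, 0.0283; 4.98 ± 0.102 against 11.3 ± 4.01, SD, n = 3). No gene of the list passed over all genes, with Kdr at an adjusted p of 0.0940, and the list did not pass (camera adjusted p = 0.172). Vegfa, the principal vessel growth factor, was at 2.23 ± 0.210 in controls and 2.87 ± 0.478 in lasered retinas (0.25, adjusted p = 0.410), from 55 to 70 reads per library. Vegfa in controls stood at 70.2 on day 7, and the cause of this gap between the days was not tested. Pgf, a related factor, was at 1.13 ± 0.114 and at 31.8, 3.18 and 5.33 (2.16, adjusted p = 0.136), and Angpt2, a modulator of vessel stability, differed by -0.27 (adjusted p = 0.555). Vegfa (ENSMUSG00000023951) lies on chromosome 17 from 46016993 to 46032369 and Kdr (ENSMUSG00000062960) on chromosome 5 from 75932827 to 75978458. Of 10 endothelial markers 1, Plvap, a protein of fenestrated endothelium, rose (0.95, list-alone adjusted p = 0.0310; camera adjusted p = 0.164). The endothelial count was 0 without control replicate 1 or 3 or lasered replicate 1 or 2, and 4 without lasered replicate 3. Without any 1 of the controls 0 angiogenic genes passed, and without any 1 of the lasered libraries 3 did.

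In all, 16 of 28 lists passed camera on day 3, 11 higher and 5 lower. None passed with an estimated correlation (smallest adjusted p = 0.521), and fry, which asks whether the genes of a list move one way on balance, passed 2, microglia and Müller glia (adjusted p = 0.00389 each).

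**Figure D1:**
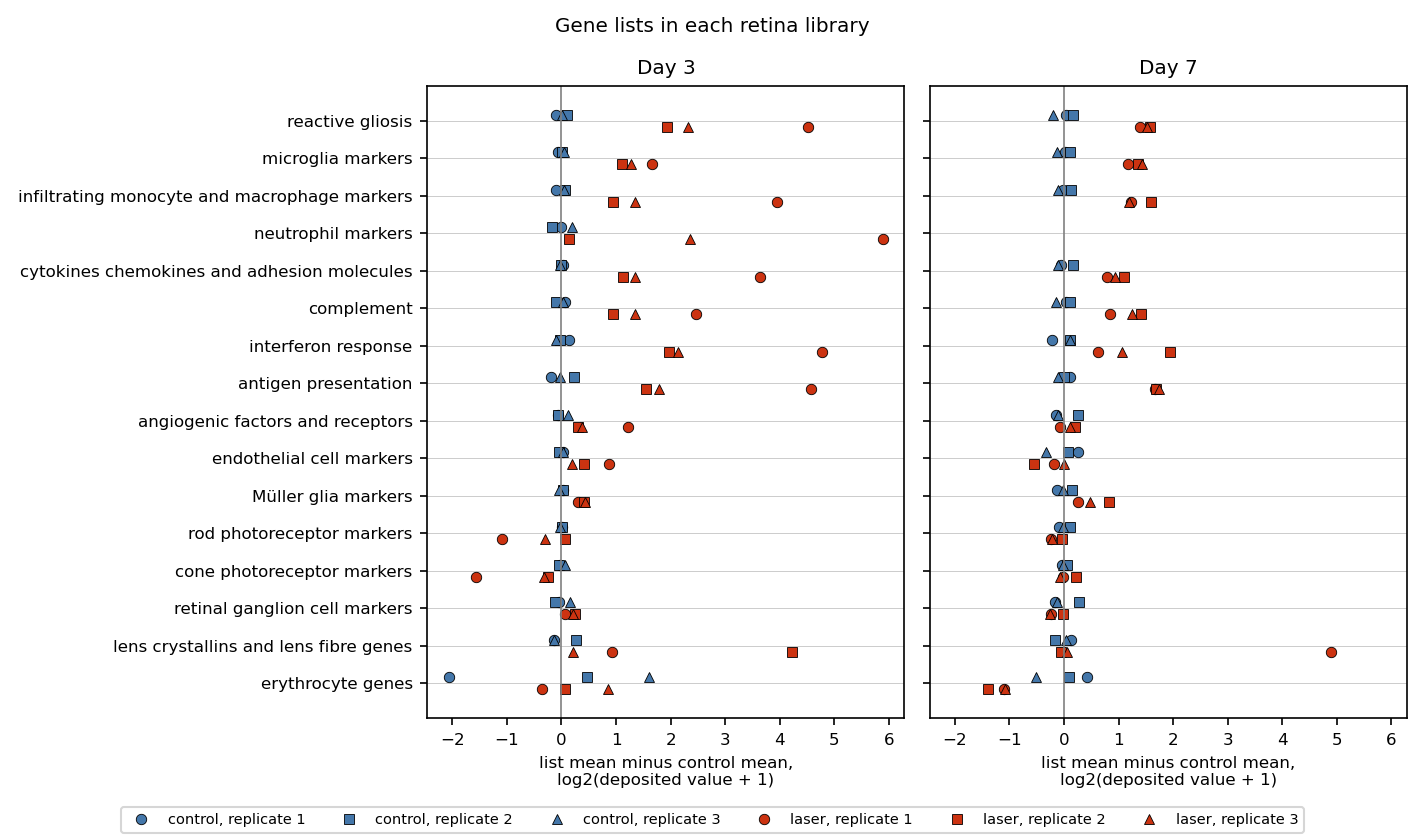
Mean of each gene list in every library minus the mean of the controls of that day, on the log2(deposited value + 1) scale, with controls in blue, lasered retinas in red and symbols for the replicate numbers; neutrophil markers had too few tested genes on day 7. On day 3 the reactive gliosis means of the lasered retinas were 4.52, 1.94 and 2.32, and on day 7 they were 1.40, 1.57 and 1.52.

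The second comparison asked the same on day 7. The lists of antigen presentation, microglia and reactive gliosis were higher relative to other genes by camera (adjusted p = 0.00977 each with an estimated correlation), and the lasered libraries lay closer together than on day 3 in most of these groups. Cd74, the invariant chain of class II molecules, went from 1.74 ± 0.321 (SD, n = 3) in controls to 42.3 ± 8.08 (SD, n = 3), and Lyz2, the lysozyme of myeloid cells, from 5.05 ± 1.98 to 88.4 ± 17.7. Gfap went from 27.0 ± 10.3 to 140 ± 22.2 and Edn2 from 19.0 ± 9.89 to 211 ± 36.4. The 4 globin genes fell over their list alone, and the list did not pass with an estimated correlation (adjusted p = 0.0547). Rod markers were lower relative to other genes by camera, with 18 of 21 below controls at a median of -0.19. None passed over the list (0 of 21), and fry made no call (adjusted p = 0.278).

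Of 15592 genes tested on day 7, 37 rose and 1 fell, and 33 of these were protein-coding. The largest rises were Cd74 (3.98, SE 0.21, adjusted p = 0.00309), Lyz2 (3.92, SE 0.27, adjusted p = 0.00444), the class II chain H2-Eb1 (3.69, SE 0.30, adjusted p = 0.00785), Edn2 (3.53, SE 0.37, adjusted p = 0.0202), the class II chain H2-Aa (3.25, SE 0.22, adjusted p = 0.00444) and Serpina3n (3.03, SE 0.28, adjusted p = 0.0137). Cd74 (ENSMUSG00000024610) lies on chromosome 18 from 60803848 to 60812646 and Lyz2 (ENSMUSG00000069516) on chromosome 10 from 117277331 to 117282321. Lyz2 has a near copy, Lyz1, and its count is uncertain for that reason. The gene that fell was Gm22751, annotated as a microRNA and chosen after its values were seen (-2.32, adjusted p = 0.0192). With only genes of at least 200 bases of exons tested, 0 fell here too. No fall with a given name passed; among those with the smallest p-values was Hba-a2, an alpha globin (-1.14, adjusted p = 0.113). In 8.89% of genes the groups did not overlap, where chance gives 10%, and 614 genes had an unadjusted p under 0.05, 490 of them higher.

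This count was 13 without the filter and 13 with voom, 22 in the joint fit, 76 with GC trends removed and 114 with library weights. Without control replicates 1, 2 and 3 it was 9, 6 and 0 (388 at an unadjusted p under 0.05 in the last), and without lasered replicates 1 and 3 it was 11 and 0 (441 at an unadjusted p under 0.05 in the last).

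Of 12 antigen presentation genes 10 rose when adjusted over the list alone and 5 over all genes, Cd74, H2-Aa, H2-Eb1, H2-K1 and H2-Ab1 (camera adjusted p = 6.87e-32; adjusted p = 0.00977 with an estimated correlation). Of 14 microglia markers 12 rose over the list and 6 over all genes, among them C1qb (1.98, adjusted p = 0.00444), Tyrobp, an adaptor of myeloid receptors (1.73, 0.0202), and C1qa (1.90, 0.0202), again with the list passing (camera adjusted p = 5.38e-34; adjusted p = 0.00977 with an estimated correlation). Aif1 was higher by 1.54 without passing over all genes (adjusted p = 0.346). Of 7 monocyte and macrophage markers 4 rose over the list, with Lyz2 and Cd68 (1.62, adjusted p = 0.0202) over all genes and Fcgr1 (1.35, list-alone adjusted p = 0.0112) over the list (camera adjusted p = 1.88e-12; adjusted p = 0.00977 with an estimated correlation). Of 10 cytokines, chemokines and adhesion molecules 6 rose over the list, such as Icam1 (1.33), Cxcl16 (0.81) and Ccl5 (2.09), each at a list-alone adjusted p of 0.00541, and 0 over all genes (camera adjusted p = 1.87e-12; adjusted p = 0.00977 with an estimated correlation). Ccl2 and Il1b did not reach the filter: their controls were listed at 0 and the lasered retinas held 20 and 9 reads in total, where 3 reads correspond to 0.259 to 0.351 for Ccl2 and 0.152 to 0.192 for Il1b.

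In reactive gliosis 14 of 18 genes rose over the list and 6 over all genes, including Serpina3n, Edn2, Timp1, an inhibitor of matrix proteases (2.75, adjusted p = 0.0202), and Gfap (2.40, adjusted p = 0.0419), with the list passing (camera adjusted p = 1.08e-33; adjusted p = 0.00977 with an estimated correlation). Of 7 complement genes 5 rose over the list and 2 over all genes, Serping1 (2.19, adjusted p = 0.00785) and C4b (2.49, adjusted p = 0.0102), while C1ra was higher by 1.37 (list-alone adjusted p = 0.00356; camera adjusted p = 9.90e-11; adjusted p = 0.0547 with an estimated correlation). C3, the central complement component, was higher by 1.23 (list-alone adjusted p = 0.00524, adjusted p = 0.365 over all genes). Of 16 interferon response genes 12 rose over the list and 1, Bst2, over all genes (2.27, adjusted p = 0.00444), with Irf9 at 1.07 (list-alone adjusted p = 0.00199) and Ifitm3 at 1.00 (0.00831; camera adjusted p = 2.11e-22; adjusted p = 0.110 with an estimated correlation). The interferon count depended on single libraries: it was 3 without control replicate 1, 6 without control 2 and 5 without lasered replicate 3. Of 12 Müller glia markers 3 rose over the list, Crym (1.26, adjusted p = 0.0243), Apoe (1.06, list-alone adjusted p = 0.0183) and Car14 (0.57, 0.0349), and the list passed (camera adjusted p = 3.99e-08; adjusted p = 0.0406 with an estimated correlation). The Müller count was 1 without control replicate 2, lasered replicate 1 or lasered replicate 3.

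Of 21 rod markers 18 had negative differences, with a median of -0.19, and 0 passed over the list (camera adjusted p = 4.85e-05; adjusted p = 0.0406 with an estimated correlation). The rod median was -0.03 without control replicate 2 and -0.11 without lasered replicate 3. Nrl, the rod transcription factor, differed by -0.41 (adjusted p = 1.00) and Guca1b, an activator of guanylate cyclase, by -0.33 (adjusted p = 1.00). Cone markers did not pass (camera adjusted p = 0.9502), though Gnb3 rose by 0.81 (list-alone adjusted p = 0.0114; not without control replicate 2 or 3 or lasered replicate 1 or 3), and their camera direction was down while their median of 0.05 (-0.09 without lasered replicate 2) and mean of 0.04 were positive. Retinal ganglion cell markers had a median of -0.15 with 0 of 12 passing, Nefh at -0.37 and Nefm at -0.56 among them (camera adjusted p = 9.83e-04; adjusted p = 0.198 with an estimated correlation). The ganglion cell call ended without control replicate 2 (median -0.03, adjusted p = 0.0603) and with library weights (0.189). All 4 tested globin genes fell when adjusted over the list alone, Hba-a2, Hba-a1 (-1.23), Hbb-bs (-1.22) and Hbb-bt (-1.18) (camera adjusted p = 1.87e-12; adjusted p = 0.0547 with an estimated correlation). Globin gene pairs are near-identical and their single counts are uncertain. Mitochondrially encoded genes had a median of -0.35 with 0 of 13 passing, mt-Cytb at -0.49 among them (camera adjusted p = 0.00275; adjusted p = 0.582 with an estimated correlation), and their lasered means of -0.81, 0.80 and -0.77 lay on both sides of the controls. The mitochondrial call ended without control replicate 1 (median -0.21, adjusted p = 0.130) and without lasered replicates 1 (-0.04, 0.364) and 3 (-0.10, 0.428), while without lasered replicate 2 the median was -0.82 and the number of its genes that fell was 10.

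Among 27 angiogenic factors and receptors 0 passed over the list on day 7, with 0 over all genes in limma as well (camera adjusted p = 0.539, direction down, with a median of -0.05 and a mean of 0.08). Fgf2 was higher by 1.87 (list-alone adjusted p = 0.0542), and 1 angiogenic gene rose without lasered replicate 1 and 2 without lasered replicate 2. Vegfa was at 70.2 ± 14.3 (SD, n = 3) in controls and 59.4 ± 13.4 in lasered retinas (-0.24, adjusted p = 1.00), Pgf at 1.31 ± 0.200 and 3.32 ± 1.07 (0.88, adjusted p = 0.777), and Angpt2 differed by 0.03 (adjusted p = 1.00), a sign that turned after rescaling (-0.02). Kdr was at 35.0 ± 12.9 and 66.3 ± 26.8 (0.89, adjusted p = 1.00) and passed with the replicate block (adjusted p = 0.0465). Endothelial markers had a median of -0.23 with 0 of 12 passing, Eng at -0.56 and Pecam1 at -0.35 among them (camera adjusted p = 0.00109; adjusted p = 0.385 with an estimated correlation). The endothelial call ended without control replicate 1 (median -0.13, adjusted p = 0.275), without lasered replicate 2 (-0.06, 0.567) and with library weights (0.979), where the list mean was 0.07, while without lasered replicate 3 the median was -0.37. Pericyte and smooth muscle markers had a median of -0.14 with 0 of 7 passing, Higd1b at -0.79 and Acta2 at -0.63 among them (camera adjusted p = 0.0377; adjusted p = 0.289 with an estimated correlation), and the pericyte and smooth muscle call ended with the replicate block (adjusted p = 0.0639), with GC trends removed (0.179, or 0.164 with the block), without the filter (0.0535), after median-of-ratios rescaling (0.0644) or quantile normalization (0.0893), in the joint fit (0.138) and with library weights (0.397). It also ended without control replicate 1 (0.282) or 2 (0.0648) and without lasered replicate 1 (0.0931) or 2 (0.279), and the median was -0.02 without control replicate 2, -0.28 without control replicate 3 and -0.23 without lasered replicate 3. Rpe65 differed by 0.54 (adjusted p = 1.00), a sign that turned with library weights (-0.77), without control replicate 1 (-0.11) and without lasered replicate 2 (-0.02).

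In all, 16 of 27 lists passed on day 7, 10 higher and 6 lower, and 7 passed with an estimated correlation. Fry passed 8, and the replicate block 14.

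**Figure D2:**
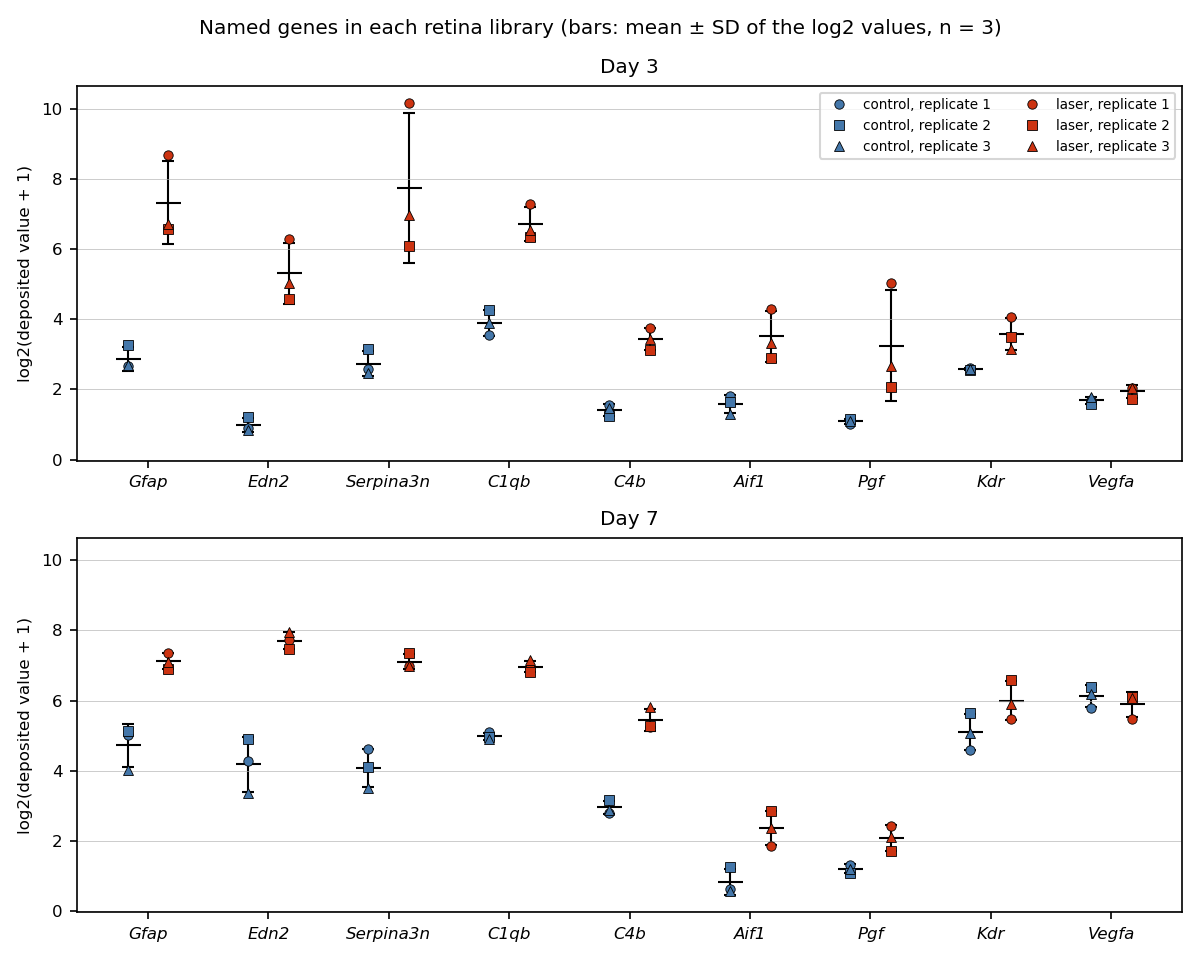
Values of 9 named genes in each retina library on day 3 and day 7 as log2(deposited value + 1), with controls in blue, lasered retinas in red, symbols for the replicate numbers, and bars for the mean ± SD of the log2 values of 3 libraries. Lasered Gfap lay above every control on both days, while Vegfa overlapped between the groups on both.

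The third comparison asked whether the effect of laser differed between the days. Gfap, Edn2, Fcrls, Crym, C1qb, C4b, CT025671.4 and the predicted genes Gm16174 and Gm37904 rose on both days. These 9 genes stand against 0.0487 expected for independent lists, from 17 and 37 rises among 12908 genes tested on both days, whose controls are separate libraries. All 37 genes that rose on day 7 had positive differences on day 3, 36 of them at an unadjusted p under 0.05. Across genes, which are not independent replicates, the log2 fold changes of the days correlated with a Pearson coefficient of 0.407 and a Spearman coefficient of 0.207.

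Of 17611 genes, 0 differed between the days in limma's interaction test (smallest adjusted p = 0.171, 1654 at an unadjusted p under 0.05). The smallest p-values were those of Gm10800 (day 7 minus day 3 -2.23, adjusted p = 0.171), Gm22751 (-3.27, 0.211), Gm11730 (-2.35, 0.255), A930015P04Rik (-1.71, 0.255) and Gm3375 (-1.51, 0.266), all predicted or unnamed genes. Gm11730, like Gm16174, is an antisense gene, whose reads cannot be told from those of its partner unless strand was used. With a pseudocount of 0.1 the test called 2 genes and without the filter 28, and without single libraries 0 to 3.

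For the gene lists, the interferon response had the smallest p: its mean difference was 2.96 on day 3 and 1.08 on day 7, a change of -1.88 (camera adjusted p = 2.69e-07). Reactive gliosis went from 2.82 to 1.40 (-1.42, adjusted p = 7.21e-06), monocyte and macrophage markers from 2.34 to 0.81 (-1.53, adjusted p = 0.00111), and neuronal injury genes from 0.98 to 0.19 (-0.78, adjusted p = 8.77e-04). The 12 monocyte markers tested here passed a filter over both days, while 7 passed that of day 7. Low markers that entered through high lasered values of day 3 can enlarge such a fall. Cone markers went from -0.71 to 0.05 (0.76, adjusted p = 7.21e-06) and rod markers from -0.44 to -0.17 (0.28, adjusted p = 8.77e-04). Microglia markers (-0.19, adjusted p = 0.963) and antigen presentation (-0.99, adjusted p = 0.0907) did not pass. In all 12 of 29 lists passed, 8 lower and 4 higher on day 7, and 0 with an estimated correlation (adjusted p = 0.556 for each list named as passing). Without lasered replicate 1 of day 3, 7 passed, with the interferon response at -0.99 (adjusted p = 5.87e-09), gliosis at -0.67 (5.18e-05), cones at 0.33 (3.17e-05) and neuronal injury at -0.53 (0.00260) among them. Monocyte markers at -0.53 (0.0729) and rods, whose sign turned (-0.05, 0.489), did not pass then. The rod call also ended after quantile normalization (0.26, adjusted p = 0.112), and the rod value was 0.53 without lasered replicate 2 of day 3. Neuronal injury did not pass without lasered replicate 2 of day 7 (-0.60, adjusted p = 0.0660).

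**Figure D3:**
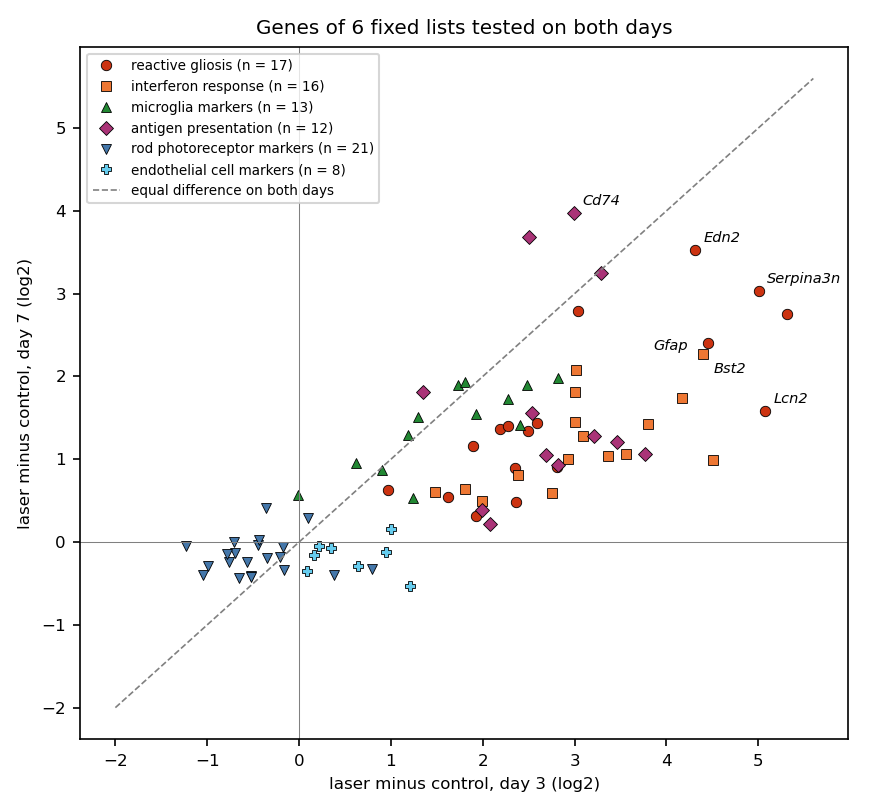
Laser minus control on day 3 (horizontal) against day 7 (vertical), both on the log2(deposited value + 1) scale, for the genes of 6 lists tested on both days, with a dashed line where both are equal. All 17 gliosis genes and 16 interferon genes lay on the day 3 side of the line, and 7 of 13 microglia genes did.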

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

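The tests of a single library as the whole response, the tests of what lowers the interferon and gliosis lists on day 7 and the list tests on the difference between the days were chosen only after the result was seen. The test of single genes for a difference between the days, the GC and photoreceptor tests of lasered replicate 1 and the other splits of the samples were written down before their results were seen. The effect of laser differed between the days for 12 of 29 lists by camera, 8 lower and 4 higher on day 7, and for 0 with an estimated correlation (smallest adjusted p = 0.556). Mean changes from day 3 to day 7 were -0.66 for endothelial markers, -1.53 for monocyte and macrophage markers, -2.58 for neutrophil markers, -1.17 for cytokines with chemokines and adhesion molecules, -1.88 for the interferon response, -1.42 for reactive gliosis, -0.78 for the neuronal injury response and -0.80 for immediate early and heat shock genes. They were 0.28 for rods, 0.76 for cones, 0.14 for bipolar cells and 0.72 for retinal pigment epithelium and melanocyte markers. Without lasered replicate 1 of day 3, 7 of the 12 still passed, the interferon response at -0.99, gliosis at -0.67, cones at 0.33 and pigment epithelium at 0.30 among them. Monocyte markers (-0.53, adjusted p = 0.0729), neutrophil markers (-1.24, 0.315), cytokines (-0.36, 0.909), rods, whose sign turned (-0.05, 0.489), and bipolar cells (0.09, 0.0635) did not pass then. Without lasered replicate 2 of day 7, endothelial markers (-0.54, adjusted p = 0.109), cytokines (-1.21, 0.124), neuronal injury (-0.60, 0.0660) and bipolar cells, whose sign turned (-0.04, 0.163), did not pass. Cytokines did not pass either without control replicate 3 of day 3 (adjusted p = 0.103) or with the cyclic factor undone (0.0528), bipolar cells without control replicate 2 of day 3 (0.0591) and rods after quantile normalization (0.112). The neutrophil call (adjusted p = 0.0491) ended in 12 alternatives: without the filter, with the cyclic factor undone and without any 1 library except control replicate 1 or lasered replicate 2 of day 3, the latter giving -3.91. These markers had too few tested genes on day 7 for a test of that day. Some of them thus entered the test between the days through their day 3 values, which can enlarge the fall. The same holds for monocyte markers (12 tested between the days, 7 on day 7) and cytokines (18 and 10). Rods were at 0.53 without lasered replicate 2 of day 3, pigment epithelium at 1.24 without lasered replicate 3 of day 3, and bipolar cells at 0.07 and 0.28 without control and lasered replicate 1 of day 7.

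Lasered replicate 1 of day 3 held more gliosis RNA than the other lasered libraries, by a median of 2.05 log2 over 19 genes. With GC trends removed the excess was 1.94 (SD over genes 1.38), which argues against a GC trend. A lower share of photoreceptor RNA would raise all other cell types alike, but markers of bipolar, amacrine, horizontal and ganglion cells lay at -0.18 (SD 0.46, 33 genes), with rods at -0.996, which argues against that share as the whole cause. For the gliosis and interferon lists the response did not rest on that library alone: 100% of the 39 genes were higher in both other lasered libraries than in every control. All of them had already risen over their lists, which made a high share likely, and they are not independent of each other. Other lists varied: lasered means were 2.30, 0.40 and 0.43 above controls for extracellular matrix, and 1.65, 1.10 and 1.27 for microglia. How strongly each eye was lasered stays open, and no biological explanation was tested.

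The interferon and gliosis lists were together less raised on day 7 than on day 3, by a mean of -1.65. Without lasered replicate 1 of day 3 it was -0.83 (standard error between libraries 0.28, interferon -0.99, gliosis -0.67), so that library may carry part of the difference, and a part remained without it. The lists were chosen after the result was seen, so this does not exclude chance. With GC trends removed the mean was -1.52, which argues against these trends as the whole cause. Control libraries of the days differed along GC content, with a Spearman correlation of -0.728 across 13065 protein-coding genes. The sample labels used here name no batch and each day has a table of its own, so a library or sequencing batch cannot be told apart from the day. The time after laser stays open among the explanations and was not tested apart from a batch. Each effect is taken against the controls of its own day, which differed for the interferon and gliosis genes named on both days. Control means on day 3 and day 7 were 6.48 and 27.0 for Gfap, 1.003 and 19.0 for Edn2, and 5.83 and 16.7 for Serpina3n. For Bst2 they were 5.18 and 14.6, and for Irf9 4.03 and 16.6. A smaller effect on day 7 thus does not by itself mean lower values in lasered retinas.

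Other splits of the 6 libraries of a day number 10 with the real one, too few for a share under 0.05. On day 3 the real split gave 25 genes and the highest other 1 (1 split of 10 as large), and 16 lists against 17 (3 of 10 as large). On day 7 it gave 38 genes against 0 (1 of 10) and 16 lists against 11 (1 of 10). Among the day 7 splits, the 3 others that part every pair of equal numbers gave at most 0 genes and 11 lists, and the 6 that do not gave the same maxima. For the difference between the days, the real count of 0 genes is reached by any split (100 of 100), so this comparison says nothing about chance. The highest other count, 255, came from 1 split, the others giving at most 4, and what sets that split apart was not examined. For its lists 50 of 100 splits gave at least the real 12, with 20 at most, so chance is not excluded for these lists. These 100 splits were drawn without regard to equal numbers.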

How the results depend on the processing

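Chosen only after the data were seen were the undone cyclic factor, voom, the GC trend, library weights, the exon length minimum and the lists on the difference between the days. Of the 25 genes on day 3, the count was 20 with a pseudocount of 0.1, 27 with 0.5, 23 at a minimum of 5, 17 without a variance trend, 31 with the factor undone and 24 with the length minimum. It was 0 without the filter, 13 after median-of-ratios rescaling, 12 after quantile normalization, 1016 in the joint fit, 3 with voom, 1 with GC trends removed and 369 with library weights. The 38 genes on day 7 became 13 without the filter, 22 in the joint fit, 13 with voom, 76 with GC trends removed and 114 with library weights, and 28 to 37 in the remaining unblocked settings except the length minimum, which gave 38. The interaction called 2 genes with a pseudocount of 0.1 and 28 without the filter. Leaving out single libraries gave 0 to 294 genes on day 3, 0 to 41 on day 7 and 0 to 3 for the interaction, and 14 to 18, 12 to 18 and 7 to 17 lists. Camera with an estimated correlation passed 0 lists on day 3, 7 on day 7 and 0 between the days, and fry 2 and 8. Angpt2 on day 7 (0.03) turned to -0.0233 after median-of-ratios rescaling, -0.0630 after quantile normalization, -0.0734 with voom, -0.0694 with GC trends removed, -0.0694 with the block as well, -0.0798 with library weights, and -0.0906, -0.0044 and -0.215 without control 1, control 3 and lasered replicate 2 (range over single libraries -0.215 to 0.195). Rpe65 on day 7 (0.54) turned to -0.770 with library weights, -0.114 without control 1 and -0.0173 without lasered replicate 2 (range -0.114 to 1.10). In each case the cause was not tested.

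With the replicate number as a block, 0 genes passed on day 3 (3491 at an unadjusted p under 0.05), also with GC trends removed (0), and 53 on day 7. On the deposited values each library of day 3 correlated best with that of its own number, by little for number 2 (0.0162 against 0.0142), as did all but number 3 on day 7. With GC trends removed number 2 of day 3 did not (-0.0064 against 0.0244), while all on day 7 did. The block also moved Kdr on day 7 past the threshold (adjusted p = 0.0465). On day 3 it ended the bipolar call (0.0668) and passed the neutrophil list (0.0424), and on day 7 it ended the pericyte (0.0639) and matrix (0.136) calls. Of the named genes in settings other than leaving out a library, 834 values on day 3 kept their side, 47 lost a call and 59 gained one, and on day 7 these were 816, 30 and 17, with 7 reversed. Gfap, Fcrls and Crym on day 3 each lost their call in 12 alternatives, left-out libraries included. Edn2, CT025671.4 and C1qb lost theirs in 9, and Ccl12 and C4b in 8. The shallower day 3 libraries (9282013 to 12515844 reads) limit low genes, where 3 reads are worth 0.445 to 0.605 per kb of exons.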

Other observations

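All tests of lens tissue were chosen only after the result was seen. The immediate early, matrix and lens lists also passed camera on day 3, none of them with an estimated correlation or by fry. Of 11 immediate early and heat shock genes 5 rose when adjusted over the list alone, among them the co-chaperone Dnajb1 (1.41, list-alone adjusted p = 0.00741), the haem oxygenase Hmox1 (3.15, 0.0145) and Ier2 (1.09, 0.0277; camera adjusted p = 0.00150; adjusted p = 0.521 with an estimated correlation). That count was 1 without control replicate 2 or 3 and 8 without lasered replicate 2. On day 7 only Hmox1 of the 13 tested passed over the list (1.04, list-alone adjusted p = 0.0499; not without control replicate 1 or 2 or lasered replicate 1 or 3), and the list did not (camera adjusted p = 0.836). Of 12 extracellular matrix genes 1, Sparc, rose on day 3 (1.052, list-alone adjusted p = 0.0104; camera adjusted p = 0.0286; adjusted p = 0.550 with an estimated correlation). Its lasered means were 2.30, 0.40 and 0.43, and the call ended without lasered replicate 1 (adjusted p = 0.131), control replicate 2 (0.0672) or control replicate 3 (0.135), at a minimum mean of 5 (0.0826) and with library weights (0.105). The matrix count was 2 without lasered replicate 1, 5 without lasered replicate 2 and 0 without lasered replicate 3. On day 7 Sparc (0.60) and Tgfbi (0.97), both matrix proteins, rose at a list-alone adjusted p of 0.0271, 2 of 14 genes (camera adjusted p = 0.0355; adjusted p = 0.168 with an estimated correlation). There the matrix call ended with the replicate block (adjusted p = 0.136), at a minimum mean of 5 (0.124), after median-of-ratios rescaling (0.0772) or quantile normalization (0.112) and in the joint fit (0.425), and without control replicate 2 (0.0921), control replicate 3 (0.117), lasered replicate 1 (0.6455) or lasered replicate 3 (0.484). The matrix count of day 7 was 1 without lasered replicate 1 or 2 and 0 without any other library.

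Lists that did not pass on either day were cell cycle (adjusted p = 0.114 on day 3, where Rrm2 rose by 1.43 at a list-alone adjusted p of 0.0412 but not when any 1 control or lasered replicate 1 was left out, the count going from 1 to 4 without lasered replicate 2 and 3 without lasered replicate 3, and 0.836 on day 7), hypoxia and glycolysis (0.796 and 0.116), circadian clock (0.114 and 0.836), amacrine and horizontal cells (0.442 and 0.357), and angiogenic factors and receptors (0.172 and 0.539). Pericyte markers did not pass on day 3 (0.796). Single libraries decided some of these: cell cycle passed on day 3 without control replicate 1 (0.0429) and the clock without lasered replicate 2 (0.0423), and on day 7 without lasered replicate 2 amacrine cells (0.0182), hypoxia (0.0287), immediate early genes (0.0287) and neuronal injury (0.0125) passed. With GC trends removed, the clock passed on day 3 (0.0183) and hypoxia on day 7 (0.0322). Erythrocyte genes did not pass on day 3 (0.484), where their control means were -2.06, 0.46 and 1.60 around the control average, and passed without control replicate 1 (2.68e-04). Y-linked genes, tested on day 3 only, had an adjusted p of 0.114 (0.0363 without control replicate 2), and skeletal muscle markers, tested on day 7 only, 0.443. On day 7 bipolar cell (0.230), neuronal injury (0.553, with Atf3 up by 0.99 at a list-alone adjusted p of 0.00416) and pigment epithelium markers (0.446, with 1 falling without control replicate 2) did not pass either. Camera pointed down while median and mean were positive for amacrine cells, hypoxia and erythrocytes on day 3 and for the clock on day 7, and pigment epithelium on day 7 had a positive median (0.11; -0.11 without control replicate 1, -0.03 and -0.04 without lasered replicates 2 and 3) with a negative mean (-0.04). Only 2 lymphocyte markers were tested on each day and 0 and 1 corneal markers, too few for a test.

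Lens genes stood out in single lasered libraries. The lens list passed on day 3 (2 of 12 rose over the list, Cryab by 1.12 and Crybb3 by 2.10, list-alone adjusted p = 0.0182 each; camera adjusted p = 0.0286; adjusted p = 0.582 with an estimated correlation) and on day 7 (0 of 16; camera adjusted p = 1.07e-05; adjusted p = 0.469 with an estimated correlation). Lasered means were 0.93, 4.23 and 0.22 on day 3 and 4.88, -0.05 and 0.05 on day 7, and the call ended without lasered replicate 1 on day 7 (adjusted p = 0.245) and without control replicate 3 on day 3 (0.172). On day 3 the lens call also ended at a minimum mean of 5 (0.0663), in the joint fit (0.221) and with the cyclic factor undone (0.0595). It did not end there without lasered replicate 2, the library with the highest mean of the list. The filter was applied anew in that fit, and genes high only in that library, such as Cryaa, dropped out. The call then rested on a smaller set of genes, Cryab among them, and does not speak for the whole list. On day 3 the number of lens genes that rose was 0 without any 1 control. Cryaa, a lens crystallin, read 157 in lasered replicate 2 of day 3 and 546 in lasered replicate 1 of day 7, against at most 1.02 in the other libraries of both days.

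Lens tissue taken along with the retina is a candidate source of these transcripts. The 4 lens fibre genes that are not crystallins, Lim2, Mip, Bfsp1 and Bfsp2, were all highest in lasered replicate 1 on day 7 (4 of 4, with 105 to 399 reads each), as that hypothesis needs. On day 3 they were all highest in lasered replicate 2 (4 of 4), but from few reads: Mip at 0.486 (7 reads, 0 elsewhere), Bfsp1 at 0.495 (8 reads, at most 0.339 elsewhere), Lim2 at 1.03 (15 reads) and Bfsp2 at 4.004 (44 reads, at most 1.51 elsewhere). The first 2 lie near the limit of reading, so the evidence is weaker for day 3. Of 16 lens genes 15 on day 3 and 16 on day 7 were highest in these libraries. Whether crystallins rose in every lasered eye was asked by the share of the list higher in each lasered library than in every control. It was 25% on day 3 (3 of 12, Cryab, Crybb3 and Cryba4) and 6.25% on day 7 (1 of 16). Many genes of the list, such as Cryaa, reached the filter only through the 1 high library, so a low share was likely beforehand. The share thus cannot decide on such a rise. Cryab, which retinal cells also express, was at 412, 244 and 232 in the lasered retinas of day 3 and 131 ± 11.9 (SD, n = 3) in controls.

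The days also differed in makeup. Mitochondrially encoded genes took 15.7% to 22.7% of the signal on day 3 and 1.10% to 4.21% on day 7, and the 10 highest genes 22.7% to 33.8% and 10.1% to 15.2%. Spearman correlations with GC content ran from -0.288 to 0.317 across libraries on day 3 and from -0.708 to 0.590 on day 7.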
